A study of Mus musculus with 11 samples.

How the data were processed

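The series holds 11 QuantSeq libraries of C2C12 cells, in which reads are primed from the poly(A) tail and each transcript is counted by tags near its 3' end. Samples were assigned to the control group (n = 6) or the Drp1 group (n = 5) by the hairpin named in their titles. Per the labels' protocols, total RNA was extracted from the cells, libraries were amplified by PCR, and reads ran forward from the tag. The read length is given as 50 bp in the sample protocol and as 75 bp in the series text, and which holds is not settled here. Per the series text, alignment was done in the BlueBee software; the aligner, the counting program, its strand setting and its annotation release are not given in the sources used here. The submitters' processing notes name GRCm38, mm10 and DESeq2 version 1.22.2. Without a stated strand setting, overlapping and antisense genes cannot be told apart in the counts.

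The deposited raw table holds whole-number counts per gene, not normalized, for 15113 genes, of which 14 had no count in any library. The second table, by the authors, holds a signal per gene that equals the raw count divided by 1 size factor per library, as found from the values. It was used only to check the authors' scaling and to recompute shares of counts. Gene identifiers were matched to symbols through a reference table; 15080 matched and 33 did not. Positions came from the GENCODE M21 annotation of GRCm38, matched by identifier. Total counts ran from 12277622 to 23082617 per library.

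Counts were tested with edgeR version 4.0.16 in R version 4.3.3: genes were filtered with filterByExpr by group, which left 13025, libraries were scaled by TMM, and a robust quasi-likelihood model with the group as its only term was tested per gene with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and standard errors of fold changes were derived from the fold change and its F statistic. Of 31 gene lists, 29 had at least 5 measured genes and were tested with camera (limma version 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The lists covered mitochondrial fission and fusion, respiratory complexes I, II with III, IV and V, genes encoded by mitochondrial DNA, the citric acid cycle, fatty acid oxidation, glycolysis, sarcoplasmic reticulum calcium, mitochondrial calcium, sarcomere, myogenic commitment and fusion, proliferation, integrated stress response, mitochondrial proteostasis, endoplasmic reticulum stress, mitophagy and autophagy, mitochondrial biogenesis, mitochondrial and cytosolic ribosome, antioxidant, cholesterol and lipid, interferon, inflammatory, extracellular matrix, p53, immediate-early, adipocyte, osteoblast and other-cell genes. Shares of counts and library sizes were compared with a two-sided exact permutation test of the difference of means over all 462 splits, whose smallest p is 0.00216.

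Design, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Dnm1l; the 10 genes with the largest fold change in each direction among those past the threshold with a mean of at least 10 CPM and no overlap between groups, without predicted genes and pseudogenes; and, of each list, the 2 members with the smallest adjusted p (4 for fission and fusion, both calcium lists and fatty acid oxidation). Genes chosen after their values were seen are, besides those so named in the text, Isg15, H2-K1, Asns, Atf4, Junb, Ier2, Prdx2, Itpr1, Tpm3, Sesn2 and Col1a1, and all genes first named in the closing parts. Some genes that the rule names are not reported here. Genes with 1 to 3 counts in a group are given as a ratio with an exact binomial interval or as levels only. No column of per-sample values was left unused.

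Alternatives were other scalings (median-ratio factors, library totals alone, upper quartile), no and a stricter low-count filter, DESeq2 version 1.42.0, limma-voom, the replicate number as a block, counts thinned to the smallest library, stricter thresholds, other set tests and leaving out each library in turn. Added after seeing the data were the share of ribosomal RNA counts as a covariate, leaving out control replicate 1 and Drp1 replicate 2 together, and leaving out the chromosome 8 segment. The replicate libraries were compared for duplicates: chi-square over degrees of freedom ran from 5.30 to 61.6 within groups, so no pair was a repeat of the same library.

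The edgeR steps were tested on simulated data for this comparison, drawn for 13025 genes with known changes. Calls were made for 18% of genes changed 1.25-fold, 50% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and 10 of 140 calls (7.14%) were false. In 5 further draws, made after the result was seen, 2.26% to 11.3% of calls were false. A planted stretch of 140 lowered genes was found in 131 of them. With no gene changed, edgeR called 1 gene, and none in the further draws, and camera called no list. Genes were simulated as independent of one another, whereas the correlation estimated within the real lists reached 0.63, for proliferation. The simulation therefore does not measure camera's error rate in these data. It also changed far fewer genes than were called in the real comparison.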

Results

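Messenger RNA was measured in C2C12 cells, a mouse skeletal myoblast line that fuses into multinucleated myotubes when serum is withdrawn. The cells were described as early-stage myotubes at passages 2 to 5. Control libraries (n = 6) carried a random short hairpin RNA and Drp1 libraries (n = 5) carried a hairpin against Drp1, the dynamin-related GTPase that divides mitochondria, encoded by Dnm1l. Total counts in control replicates 1 to 6 were 15702942, 23082617, 18320363, 18982757, 15882963 and 20412598, and in Drp1 replicates 1 to 5 they were 16591621, 12277622, 18333694, 20706327 and 16977761. Depth differed between the groups by less than the spread between libraries (two-sided exact permutation test, p = 0.361). The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

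Dnm1l was lower in every Drp1 library than in any control library. Its level was 78.6 ± 8.63 CPM (SD, n = 6) in control and 18.7 ± 2.58 CPM (SD, n = 5) in Drp1 libraries, which left 23.7% of the control mean. The log2 fold change was -2.07 (SE 0.11, adjusted p = 2.7e-10, edgeR quasi-likelihood test). Dnm1l (ENSMUSG00000022789) lies on chromosome 16 from 16312230 to 16358959 on the minus strand of GRCm38, and the 3' tags counted here fall at the end of the transcript.

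The question set by the series title is how Drp1 affects substrate oxidation and calcium handling in muscle. The difference between the cultures reached far beyond those topics: contractile genes such as Tnnc1 fell by orders of magnitude, while the smooth muscle gene Cnn1 and interferon-stimulated genes such as Ifi44 rose. Of 13025 genes tested with edgeR, 4413 were higher and 4332 lower in Drp1 libraries, and 4280 did not pass an adjusted p of 0.05. At least 2-fold changes were seen in 1461 higher and 1786 lower genes, and at least 8-fold changes in 216 higher and 719 lower genes. The libraries of the groups did not overlap for 6368 genes (48.9%), where chance gives 0.433%. The first principal component held 87.9% of the variance and separated the groups.

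The genes with the largest decreases included developmental regulators and a potassium channel. Sox11, a transcription factor of progenitor cells, fell from 614.9 ± 37.4 CPM (SD, n = 6) to 0.562 ± 0.352 CPM (SD, n = 5). The chemokine Cxcl14 fell from 77.5 to 0.0756 CPM and the polysialyltransferase St8sia2 from 111.9 to 0.121 CPM. The imprinted cell cycle inhibitor Cdkn1c fell from 39.4 to 0.0756 CPM, the muscle RNA-binding protein Rbm24 from 294.3 to 0.670 CPM, Filip1 from 40.1 to 0.0907 CPM, R3hdml from 269.8 to 0.832 CPM and that channel, Kcnn3, to 0.0645 CPM, a log2 fold change of -8.29. For the receptor Erbb3, 2 counts remained in the Drp1 libraries, both in replicate 2, and the ratio of control to Drp1 was 836.6 (95% exact binomial interval 231.3 to 6912, counting error only, since PCR reads were not marked with molecular identifiers). Without that library no Drp1 count of Erbb3 remained. Adjusted p-values of these genes in edgeR ran from 5.3e-15 for Rbm24 to 1.9e-11 for Kcnn3. In all Drp1 libraries together Kcnn3 had 5 counts, Cxcl14 and Cdkn1c 7 each and Filip1 8, so the sizes of their changes are uncertain.

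The genes with the largest increases included a smooth muscle gene and several interferon-stimulated genes. Cnn1, the smooth muscle calponin, rose from 4.09 ± 1.09 CPM (SD, n = 6) to 237.2 ± 26.9 CPM (SD, n = 5). Pet2 rose from 3.21 to 255.2 CPM, Glipr1 from 1.40 to 59.8 CPM, Erc2 from 0.468 to 41.8 CPM and the G protein subunit Gnai1 from 0.0404 to 22.2 CPM. Among interferon-stimulated genes, Trim30a rose from 0.128 to 45.7 CPM, Ifi44 from 0.194 to 50.6 CPM, Ifit1 from 0.951 to 59.1 CPM and Ifit3 from 0.634 to 24.6 CPM. The adhesion gene Cntn3 had 3 counts in the control libraries, 1 in replicate 2 and 2 in replicate 3, and the ratio of Drp1 to control was 1359 (95% exact binomial interval 464.5 to 6592). Without control replicate 3, only the 1 control count of Cntn3 in replicate 2 remained. For Gnai1 the log2 fold change was 8.99, and 3 of 4 control counts were in control replicate 1. Without that library 1 control count was left, so the size of its change is uncertain. Ifit1, Ifit3 and Trim30a have close paralogs, so the division of reads among family members is uncertain. Adjusted p-values in edgeR ran from 6.5e-15 for Pet2 to 1.2e-08 for Ifit1.

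**Figure D1:**
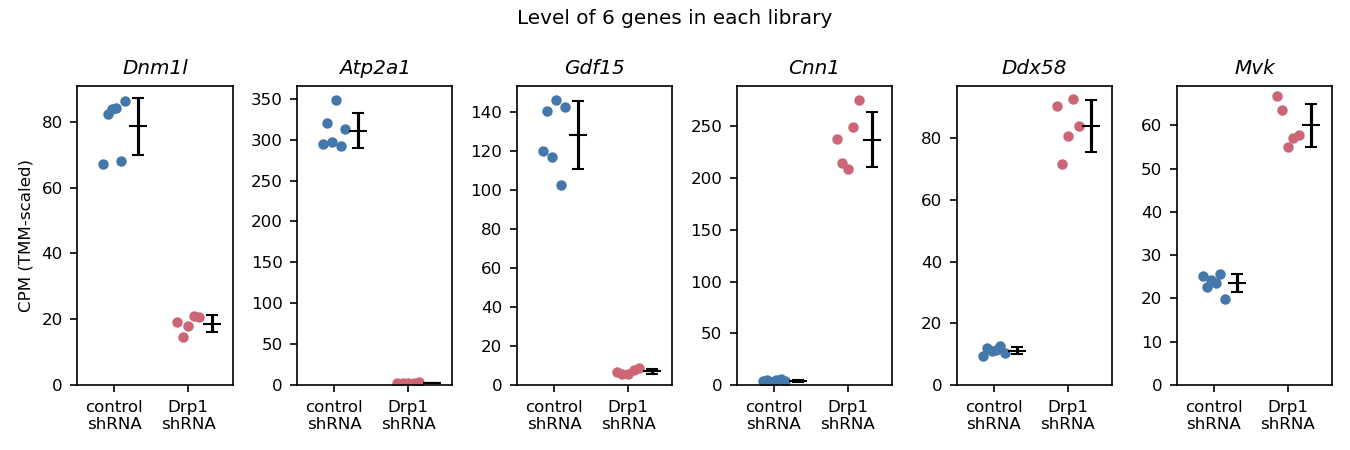
Level of 6 genes in each library, in CPM with TMM scaling on a linear axis from 0; points are libraries, and bars show the mean and SD of the 6 control and 5 Drp1 libraries. Dnm1l, Atp2a1 and Gdf15 were lower, and Cnn1, Ddx58 and Mvk higher, in every Drp1 library than in any control library.

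Genes of striated muscle fell together. Of 47 measured sarcomere genes, 46 fell and 1, Tpm3, rose, with a median log2 fold change of -6.20 (camera on the edgeR fit, adjusted p = 3.2e-75). Tnnc1, the slow troponin C, fell from 1450 ± 110.7 CPM (SD, n = 6) to 10.8 ± 0.658 CPM (SD, n = 5), myoglobin (Mb) from 328.2 to 1.97 CPM and skeletal actin (Acta1) from 5617 to 46.2 CPM. The sarcomere list took 2.82% ± 0.0984 (SD, n = 6) of counts in control and 0.462% ± 0.0477 (SD, n = 5) in Drp1 libraries (two-sided exact permutation test, p = 0.00216, the smallest that the 462 splits allow). Of 33 genes of myogenic commitment and fusion, 28 fell and 3 rose, with a median of -2.75 (camera, adjusted p = 3.6e-28). The fusion genes Mymx and Mymk fell from 248.0 to 1.08 CPM and from 1118 to 5.33 CPM, and the fetal acetylcholine receptor subunit Chrng from 593.2 to 8.73 CPM. Myogenin (Myog), which drives differentiation, fell from 1337 to 6.58 CPM, and Myod1, which commits cells to the lineage, from 120.5 to 2.28 CPM. Acta1, Mymk, Myog and Myod1 were chosen after their values were seen.

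Calcium handling genes of the sarcoplasmic reticulum and the triad moved mostly down. Of 54 measured, 29 fell and 11 rose, with a median of -0.41 and a mean of -1.80 (camera, adjusted p = 2.8e-09). The calcium pump Atp2a1 fell from 311.2 ± 21.4 CPM (SD, n = 6) to 2.57 ± 0.458 CPM (SD, n = 5), the channel subunits Cacng1 from 450.1 to 4.17 CPM and Cacnb1 from 142.8 to 2.88 CPM, and the calcium-binding protein Hrc from 124.9 to 1.54 CPM. Among those that rose, the calcium release channel Itpr1 was up by 1.54 on the log2 scale (adjusted p = 1.2e-07, edgeR). Of 22 genes of mitochondrial calcium transport, 14 fell and 3 rose (median -0.38), and the list was not past the threshold (camera, adjusted p = 0.203). Within it the uniporter pore Mcu fell from 283.6 ± 18.3 CPM (SD, n = 6) to 116.5 ± 4.05 CPM (SD, n = 5), Hspa9 from 765.9 to 349.9 CPM and the outer membrane channel Vdac3 from 107.0 to 60.2 CPM. The uniporter regulator Smdt1, chosen after its values were seen, was at 213.5 and 210.7 CPM (adjusted p = 0.812, edgeR), and the sign of its change differed between scalings. With limma-voom the mitochondrial calcium list passed (adjusted p = 0.020).

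Changes in mitochondrial genes were smaller and went both ways. Of 28 genes of mitochondrial fission and fusion, Dnm1l included, 15 fell and 4 rose (median -0.21, camera adjusted p = 0.230). Mtfp1, a fission factor, fell from 6.75 to 0.895 CPM, Dnm2 from 94.5 to 51.4 CPM and Mtfr1l from 136.6 to 77.6 CPM. Nuclear genes of the respiratory chain fell in 23 of 36 cases for complex I with 3 higher (adjusted p = 0.230), in 9 of 14 for complexes II and III with 1 higher (0.248), in 8 of 15 for complex IV with 1 higher (0.068) and in 10 of 16 for complex V with 1 higher (0.610, all by camera). The muscle isoforms Cox6a2 and Cox8b of complex IV had log2 fold changes of -6.38 and -6.74, and Uqcrq of complex III and Atp5d of complex V of -0.94 and -0.78. Ndufb7 of complex I fell by 1.43 and lies in a lowered segment of chromosome 8, and Ndufv3 rose by 0.79. The list of genes encoded by mitochondrial DNA holds 13 protein-coding genes. Of the 7 measured, 6 rose and none fell (median 0.55, camera adjusted p = 0.056). The list's share of counts was 1.17% ± 0.143 (SD, n = 6) in control and 1.78% ± 0.198 (SD, n = 5) in Drp1 libraries (two-sided exact permutation test, p = 0.00216). All 19 tested genes of the mitochondrial chromosome had a median log2 fold change of 0.04. Most of them are not on this protein-coding list, and counting from poly(A) tails may not measure them alike. That median therefore does not show how far the rise of the protein-coding genes extended. For mt-Co1 and mt-Nd5 the log2 fold changes were 1.20 and 1.14. Mitochondrial transcripts overlap and have nuclear copies, so the levels of single genes are uncertain. The call of the mitochondrially encoded list depended on the setting. It passed with no low-count filter (camera, adjusted p = 0.033), DESeq2 (0.030), limma-voom (0.016) and counts thinned to the smallest library (0.047), without control replicate 5 (0.039), Drp1 replicate 2 (0.024) or Drp1 replicate 3 (0.049), and without control replicate 1 and Drp1 replicate 2 together (0.030). Complex IV passed with no low-count filter (adjusted p = 0.042), DESeq2 (0.039) and the replicate number as a block (0.026), and without control replicate 5 (0.039) or Drp1 replicate 3 (0.041). With an estimated correlation neither list passed (camera, adjusted p = 0.546 for the mitochondrially encoded list and 0.558 for complex IV). With limma-voom the lists of fission and fusion (adjusted p = 0.020), complex I (0.0083) and complexes II and III (0.020) passed as well. With an estimated correlation on the edgeR fit they did not (camera, adjusted p = 0.361, 0.797 and 0.546).

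Genes of substrate oxidation moved in both directions, with more members lower than higher in each of 3 lists. By fry, these lists moved on balance lower (adjusted p = 2.2e-07 for fatty acid oxidation, 0.0026 for the citric acid cycle and 8.4e-09 for glycolysis). This does not set them apart, since 26 of the 29 lists passed fry. Fission and fusion (fry, adjusted p = 1.4e-10) and mitochondrial calcium (2.2e-07), not past camera, were lower by fry too. Of 32 genes of fatty acid oxidation, 10 rose and 12 fell (median -0.04, camera adjusted p = 0.419). Acsl6, an acyl-CoA synthetase, fell from 13.5 to 0.0451 CPM, the fatty acid binding protein Fabp3 from 19.6 to 2.10 CPM, the dehydrogenase Acadl from 227.4 to 108.9 CPM and Ucp2 from 43.0 to 17.5 CPM. Acsl6 had 4 counts in all Drp1 libraries together, so the size of its change is uncertain. Of 32 genes of the citric acid cycle and pyruvate dehydrogenase, 7 rose and 16 fell (median -0.20, adjusted p = 0.741). The dehydrogenase phosphatase Pdp2 rose from 6.33 to 22.7 CPM and the opposing kinase Pdk3 from 26.6 to 68.9 CPM. Among 31 genes of glycolysis 16 fell and 9 rose, with a median of -0.26 (camera, adjusted p = 0.027, and adjusted p = 0.146 with an estimated correlation). The call was also lost with a stricter low-count filter (adjusted p = 0.076) and with limma-voom (adjusted p = 0.068). Muscle glycogen phosphorylase (Pygm) fell from 63.3 to 0.587 CPM and the lactate carrier Slc16a3 from 32.9 to 3.74 CPM.

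Genes of the integrated stress response were lower in Drp1 libraries. Of 41 measured targets of this ATF4-driven programme, 37 fell and none rose (adjusted over the list alone, 37 fell and 1, Sesn2, rose, as it did at an unadjusted p under 0.05), with a median of -1.45 (camera, adjusted p = 4.1e-13, and adjusted p = 0.146 with an estimated correlation). Vldlr fell from 90.8 ± 9.62 CPM (SD, n = 6) to 0.592 ± 0.326 CPM (SD, n = 5), and the stress cytokine Gdf15 from 128.2 ± 17.6 CPM to 7.03 ± 1.33 CPM. Asparagine synthetase (Asns) fell by 1.45 and Atf4 itself fell by 1.48 on the log2 scale. Mitochondrial chaperones and import factors fell in 18 of 30 cases and rose in 4 (camera, adjusted p = 0.330), with Timm10 at -1.16. In the endoplasmic reticulum stress list, 11 of 25 genes rose and 6 fell (adjusted p = 0.792), with Herpud1, which lies in the chromosome 8 segment, at -2.97 and Atf6 at -1.01. The lists of mitophagy and autophagy (4 rose and 16 fell of 31, adjusted p = 0.248), mitochondrial biogenesis (2 and 13 of 25, 0.330), mitochondrial ribosome (14 and 34 of 74, 0.610) and cytosolic ribosome (11 and 21 of 78, 0.854) were not past the threshold by camera, although mitochondrial biogenesis passed with limma-voom (adjusted p = 0.037). Adjusted over the list alone, 5 cytosolic ribosome genes rose and 18 fell. Log2 fold changes were -4.37 for Trim63, a muscle ubiquitin ligase, -0.99 for Map1lc3a, -2.23 for Ppargc1b, -0.77 for Nfe2l1, -0.76 for Mrpl13, -0.73 for Mrpl3, -0.86 for Rpl14 and -0.64 for Rps25.

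Most interferon-stimulated genes rose, and cholesterol and lipid synthesis genes moved both ways, with more higher than lower. Of 31 interferon genes, 28 rose and 1, the class I histocompatibility gene H2-K1, fell, with a median of 2.32 (camera, adjusted p = 1.9e-12, and adjusted p = 0.140 with an estimated correlation). The RNA sensor Ddx58 rose from 11.1 ± 1.13 CPM (SD, n = 6) to 83.8 ± 8.44 CPM (SD, n = 5) and Isg15 from 6.14 to 49.1 CPM. H2-K1 fell from 68.2 to 24.9 CPM and belongs to a family of near-identical genes, so its count is uncertain. Of 37 genes of cholesterol and lipid synthesis, 22 rose and 6 fell, with a median of 0.55 (camera, adjusted p = 0.0051, and adjusted p = 0.513 with an estimated correlation). Acly, which supplies acetyl-CoA, rose from 54.0 to 128.3 CPM and mevalonate kinase (Mvk) from 23.5 to 60.1 CPM.

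Immediate-early and heat shock genes fell in 16 of 23 cases and rose in 5 (median -0.80, camera adjusted p = 0.014, and adjusted p = 0.140 with an estimated correlation). Klf4 fell by 1.75 and Hspa1a fell by 4.62 on the log2 scale. Junb fell by 2.63, Ier2 fell by 1.99, and both lie in the chromosome 8 segment. Without the segment's genes the list was no longer past the threshold (camera, adjusted p = 0.082). Among 17 inflammatory genes 9 rose and 4 fell (adjusted p = 0.248), with log2 fold changes of 2.15 for Cxcl12 and -6.35 for Il1b. Il1b had 5 counts in all Drp1 libraries together, so the size of its change is uncertain. Of 43 extracellular matrix genes 24 rose and 15 fell (adjusted p = 0.419), with values of 3.12 for periostin (Postn), 1.47 for Col1a1 and -2.62 for Mmp2, which lies in the segment. The lists of p53 targets (12 rose and 8 fell of 23, adjusted p = 0.793; 14 and 8 adjusted over the list alone) and antioxidant NRF2 targets (16 and 16 of 39, 0.957) were not past the threshold by camera. In these lists the log2 fold changes were -3.45 for Pmaip1, -3.50 for Gadd45a, -4.37 for Gpx3 and -2.72 for Sod3.

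Cell cycle genes were higher in part. Of 43 proliferation genes 20 rose and 1 fell (median 0.43, camera adjusted p = 0.079), with E2f1 up from 21.2 to 38.6 CPM and Ccne1 from 5.96 to 17.6 CPM. Their share of counts was 0.150% ± 0.0166 (SD, n = 6) in control and 0.202% ± 0.0477 (SD, n = 5) in Drp1 libraries (two-sided exact permutation test, p = 0.0433), and the groups overlapped. With single libraries left out the difference was 0.0392 to 0.066 percentage points, against 0.0523 with all, and the call was lost for 9 of 11 libraries, with p up to 0.0952. The list's camera test passed with limma-voom (adjusted p = 0.016) and without Drp1 replicate 3 or Drp1 replicate 4 (adjusted p = 0.034 and 0.016). Markers of other cell types gave few measured genes. In the list of blood, immune and other cells 1 of 7 rose and 5 fell (camera, adjusted p = 0.363), with Lyz2 up from 0.590 to 10.9 CPM and the haemoglobin gene Hba-a1, which has a near-identical copy, down from 6.27 to 0.259 CPM. Of 3 adipocyte and 3 osteoblast markers, 1 rose and 2 fell in each, too few for a set test; log2 fold changes were -0.65 for Cebpa, -0.66 for Lpl, -3.98 for Bglap2 and 3.26 for Phex.

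**Figure D2:**
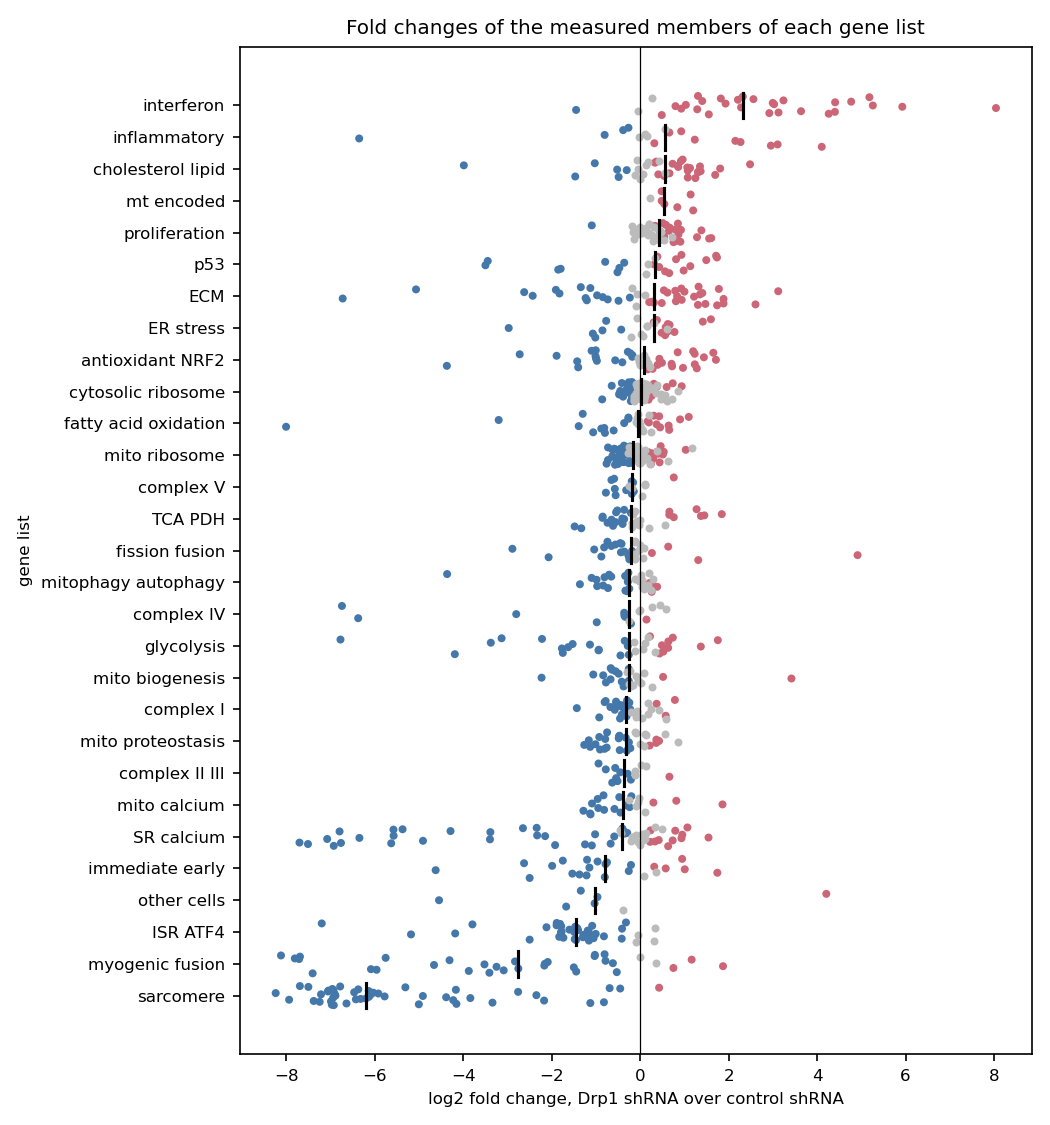
Log2 fold changes of Drp1 over control libraries (horizontal axis) for the measured members of the 29 lists with at least 5 measured genes (vertical axis, ordered by median). Red points rose, blue points fell and grey points did not pass an adjusted p of 0.05 in edgeR, and black bars are list medians, which ran from -6.20 for sarcomere genes to 2.32 for interferon genes.

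Of the 29 lists tested, 8 were past the threshold by camera, 2 higher and 6 lower. With a correlation estimated for each list the calls of sarcomere (adjusted p = 0.0024), myogenic commitment and fusion (adjusted p = 0.0024) and sarcoplasmic reticulum calcium genes (adjusted p = 0.040) held and the other 5 did not. No further list passed in that setting, those that passed with limma-voom included. In 62 of 100 groupings of the libraries into 6 and 5, the real one included, at least as many lists passed; many of these groupings carry part of the real difference, so the number is no clean measure of chance. Counts adjusted over the list alone equalled those over all genes tested wherever no second count is given. By fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, 26 lists passed, and 29 passed its test for change in either direction. Median and mean differed in sign for antioxidant targets (0.09 and -0.09), extracellular matrix (0.31 and -0.0047) and p53 targets (0.34 and -0.04). Fry gave a lower direction, against a median above 0, for antioxidant, p53, endoplasmic reticulum stress and cytosolic ribosome genes. Only the antioxidant list passed fry (adjusted p = 0.019). The others did not (fry, adjusted p = 0.834 for p53, 0.828 for endoplasmic reticulum stress and 0.459 for cytosolic ribosome), so their direction is not established.

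A stretch of chromosome 8 was lower as a whole. Between positions 78869386 and 100032102 of GRCm38, 116 of 142 tested genes fell, 9 rose and 17 did not pass, with a median log2 fold change of -1.10, while the 50 genes on either side had medians of 0.17 and 0.26. Among the segment's genes are Junb, Ier2, Mmp2, Herpud1, Ndufb7 and Prdx2. Its median in single libraries, relative to the control mean and over its 102 genes at a mean of at least 10 CPM and on none of 5 muscle and stress lists, was -1.20 to -1.10 in Drp1 and -0.0329 to 0.0391 in control libraries. The segment was chosen after the values were seen, by a running median of 25 genes under -0.5. Among 251 windows of 50 genes over the genome, 2 had medians beyond those of all 1000 shuffles of the genes. A smaller shift over a longer region would not pass this limit. The 420 tested genes of chromosome 12 had a median of -0.32, the lowest of any chromosome. Each of its windows had a median below 0, down to -0.60, and none lay beyond all shuffles.

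**Figure D3:**
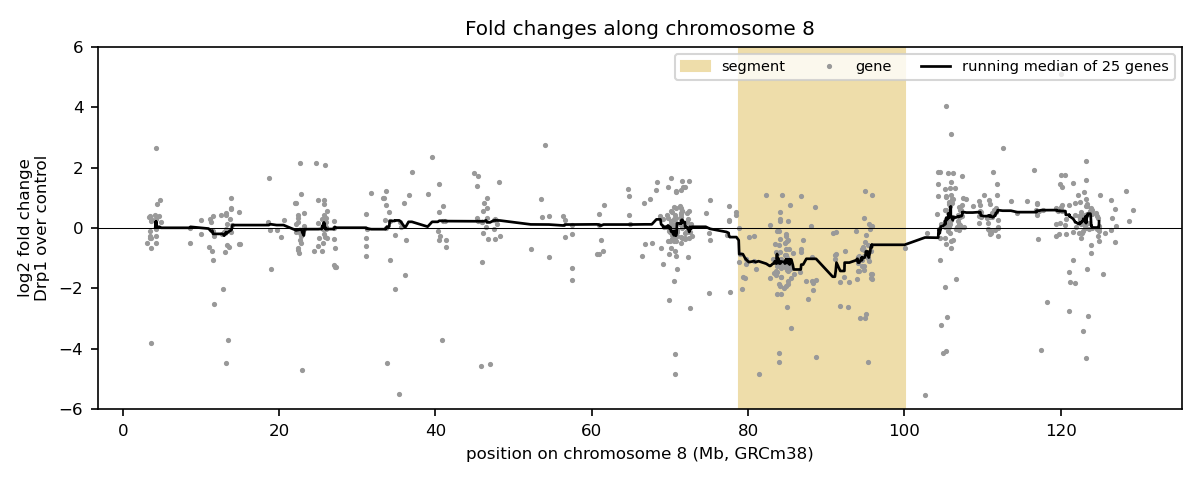
Log2 fold changes of Drp1 over control libraries along chromosome 8 (position in Mb, GRCm38); grey points are 676 genes, with 11 beyond the axis limits not drawn, the line is the running median of 25 genes, and the shaded part is the segment. The running median lies mostly close to or above 0 outside the segment and near -1.10 within most of it.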

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

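Of the tests in this part, the comparisons of the second principal component with shares of ribosomal RNA counts and with total counts, and the division of groupings by their number of Drp1 libraries, were chosen after the result was seen; the regrouping of libraries and the thinning test were not.

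A library far from the others of its group was found in 22 of 310 groups of values examined (7.10%), where chance gives about 1 in 20 for normally distributed values. That rate is a rough guide only, since the values share the same libraries. Groups with a count in only 1 library, as for Erbb3, Gdap1, Hoxb7 and Hoxb13, are always flagged. Control replicate 4 stood apart for 8 values. It was high for St8sia2 (137.8 CPM), Mb (374.0 CPM), Lmod1 (10.4 CPM), Xist (293.4 CPM), Ryr1 (130.4 CPM) and Gdap1 (0.111 CPM), and low for Klf4 (89.4 CPM) and Myog (952.2 CPM). Drp1 replicate 2 was high for Nfe2l1 (206.2 CPM), Mrpl3 (31.9 CPM), Gadd45a (32.6 CPM), Mcm4 (39.7 CPM) and Erbb3 (0.155 CPM). Control replicate 1 was high for Gnai1 (0.191 CPM) and Fgf21 (16.3 CPM), and low for Uqcrc1 (127.4 CPM) and for the share of ribosomal RNA counts (4.14%). Control replicate 6 was high for Ifit1 (2.06 CPM), control replicate 3 for Eln (5.56 CPM), and Drp1 replicate 1 for Hoxb7 and Hoxb13 (0.058 CPM each, 1 count). Drp1 replicate 4 was low for Ppargc1a (1.18 CPM). Without Drp1 replicate 2 the log2 fold change of Mcm4 was 1.01, against 1.38 with it. Without control replicate 4 that of Xist was 0.33 and passed (edgeR, adjusted p = 0.0072), against 0.19 with it (adjusted p = 0.229).

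Within groups, libraries spread along the second component (4.95% of the variance), from -30.9 in control replicate 1 and -32.5 in Drp1 replicate 2 to 27.3 in control replicate 4 and 27.7 in Drp1 replicate 5. After centring each group, this component correlated with the share of ribosomal RNA counts over 11 libraries (Pearson r = 0.879, permutation p = 0.00043, adjusted over 2 relations 0.00086; Spearman rho = 0.827, permutation p = 0.0026), and r was 0.843 without the 2 libraries farthest from the median share. With the total count the component correlated less (Pearson r = 0.598, permutation p = 0.052, adjusted over 2 relations 0.052; Spearman rho = 0.518, permutation p = 0.108; r = 0.517 without the 2 libraries farthest from the median total). Sampling noise from unequal depth is argued against as its source, since the component in counts thinned to the smallest library correlated at 1.000 with that in the full counts. Thinning does not exclude a library quality that goes along with depth. An RNA quality or priming difference that also sets the ribosomal share may lie behind the component; no biological explanation was tested. The share itself did not separate the groups (6.41% ± 1.16 in control, n = 6, and 6.30% ± 1.79 in Drp1 libraries, n = 5, SD, two-sided exact permutation test p = 0.833).

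Of 100 groupings of the libraries, 1, the real one, gave 4413 higher genes (highest other 2643), and 1 gave 4332 lower genes (highest other 3144). This argues against a random division of these libraries as the source of the gene counts. It cannot exclude a difference between the cultures that arose apart from the hairpin, since other groupings mix libraries of both groups. The groupings that came closest set 5 control libraries against the sixth control and all 5 Drp1 libraries, and so kept most of the real difference. In these the group of 5 was control, so their higher genes were higher in control libraries, opposite to the real comparison. For the number of lists moved, 8, the regrouping does not settle whether chance gave it, and it does not test any single list. At least as many moved in 62 of 100 groupings (highest other 21), but groupings with unequal proportions of Drp1 libraries carry part of the real difference. With 2 Drp1 libraries in the group of 5, the most even division, it was 11 of 40 groupings.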

How the results depend on the processing

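The covariate for ribosomal RNA, leaving out 2 libraries together and leaving out the chromosome 8 segment were chosen after the data were seen. No gene called in the comparison was called in the opposite direction under any of these settings. Counts of genes stayed within 1.5 times the values given except at a minimum of 1.5-fold (2699 higher, 2682 lower), which is stricter by construction. Library totals alone shifted the median log2 fold change by 0.0996 (5207 higher, 3751 lower) and upper quartile scaling by 0.085 (5110 and 3817), which raised the share of calls that were higher from 50.5% to 58.1% and 57.2%. Lists moved numbered 14 by limma-voom, 3 with an estimated correlation and 26 by fry. The estimated correlation replaced the preset 0.01. For the lists that lost their call, estimates ran from 0.017 (glycolysis) to 0.30 (integrated stress response). Fission and fusion, estimated at -0.022, under the preset, also went from an adjusted p of 0.230 to 0.361 by camera. Whether the size of the estimates alone cost the lost calls was not tested. Fry asks another question, as it does not compare a list with other genes. The cause of the limma-voom number was not tested. Fry gave antioxidant targets a lower direction (adjusted p = 0.019). Smdt1 and Hoxa9, not called, changed sign: Smdt1 to 0.0803 with library totals, 0.0659 with upper quartile and 0.016 without control replicate 1 and Drp1 replicate 2, and Hoxa9 to 0.0388 and 0.0256 with those scalings. Leaving out single libraries, Smdt1 ran from -0.0565 to 0.0073 and Hoxa9 from -0.114 to 0.0148. The difference in the share of proliferation genes ran from 0.0392 to 0.066 percentage points and lost its call in 9 of 11 cases. Thinning to the smallest library left 4187 higher and 4103 lower, so depth is not what sets these counts.

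Replicate numbers do not pair the samples: same-numbered libraries correlated at -0.18 to 0.36 in their deviations from the group means. With the number as a block, 3934 genes were higher and 4003 lower, and Smdt1 was at 0.0033. Over the 5 pairs the block gave differences of 0.581 percentage points for genes encoded by mitochondrial DNA (p = 0.0625, exact sign-flip test), -2.34 for sarcomere genes (p = 0.0625) and 0.0496 for proliferation genes (p = 0.188); 5 pairs cannot go below 0.0625.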

Other observations

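The other scalings used in this part were planned as alternatives; the tests of explanations, that by library totals included, and of the regions and lists first named here were chosen only after the result was seen. The lists of smooth muscle, imprinted, HOX and myoblast genes were drawn up then.

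Of 11 measured smooth muscle contractile genes, 9 rose and 1 fell, with a median log2 fold change of 1.66; no set test was run on this list. Smooth muscle actin (Acta2) rose from 2687 ± 225.8 CPM (SD, n = 6) to 7975 ± 796.4 CPM (SD, n = 5), myosin light chain kinase (Mylk) to 338.6 CPM, a log2 fold change of 5.08, enteric actin (Actg2) from 32.6 to 585.9 CPM and Lmod1 from 7.58 to 163.8 CPM, while Synpo2 fell from 112.8 to 10.2 CPM. Imprinted genes moved both ways: of 21 measured, 12 rose and 5 fell (median 0.47, mean -0.19), with Peg10 up from 20.9 to 77.3 CPM and Igf2 and H19 down from 164.5 to 36.7 CPM and from 6660 to 2787 CPM.

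The HOX clusters, whose activity records the body position a cell came from, differed by cluster. All 6 measured Hoxb genes fell, with Hoxb13 at 181 counts in control and 1 in Drp1 libraries and Hoxb7 at 130 and 1, both single counts in Drp1 replicate 1. The Hoxb median was -5.85, or -5.07 with a gene lacking any Drp1 count at its bound of 3 counts over the group. Of 9 Hoxa genes 2 rose and 2 fell (median -0.06), and of 9 Hoxc genes 6 rose and 2 fell (median 0.50). Hoxa10 was at 42.4 CPM in control and 64.8 CPM in Drp1 libraries, and Hoxa9 at 42.3 and 40.7 CPM, a difference whose sign changed with library totals alone (0.0388 on the log2 scale) and upper quartile scaling (0.0256).

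For the loss of the myogenic genes, the values go against a larger share of undifferentiated myoblasts that express the myoblast genes. Of 8 myoblast genes 7 fell and 1, Myf5, rose, with a median of -2.43, and the satellite cell gene Pax7 went from 17.8 to 0.0614 CPM. In the other direction, 20 of 43 proliferation genes rose and 1 fell. All 8 myoblast genes were also expressed in the control libraries, and several stand on the commitment and fusion list too. As the myoblast list was also drawn up after the values were seen, its fall is no independent test. Undifferentiated cells that lost these genes are not excluded. Count scaling, which moves all genes of a library alike, is argued against by the median of all genes. With library totals alone it was 0.13, where the sarcomere median was -6.10. The change of scaling by itself decides nothing, as it shifted the median of all genes by only 0.0996. A takeover by cells of another lineage or clone and an effect of lowered Drp1 on the lineage itself cannot be told apart. The hairpin and the history of the culture coincide in every library. The Hoxb median of -5.85 does not decide between them, also because Hoxb was picked after its values were seen. The medians of Hoxa and Hoxc were -0.06 and 0.50.

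For the chromosome 8 segment, count scaling is argued against by 2 of 251 fixed windows of 50 genes over the genome, both in the segment, whose medians (-1.14 and -1.04) lay beyond those of all 1000 shuffles, since scaling moves all genes of a library alike. A clustering of muscle genes stays open. Of the segment's 142 genes, 1 is on the sarcomere, commitment or sarcoplasmic reticulum calcium lists, but muscle genes on no list may lie there. The median of -1.17 over its 102 genes outside the muscle and stress lists decides nothing, as the segment was picked for low values. A loss of DNA copies may also explain it: the less and the more abundant of those genes had medians of -0.98 and -1.25, which are subject to that choice too. Clustering, loss of copies and silencing of the region cannot be told apart from RNA counts alone. A DNA copy number measurement of both cultures would test the loss of copies, and would not separate clustering from silencing.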
